A study of Mus musculus with 4 samples.

How the data were processed

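Gene expression was measured in mouse CD4 T cells on Illumina bead arrays, on which each probe is read as the mean brightness of many beads that carry the same oligonucleotide. Each of 4 groups had 1 array: conventional induced regulatory T cells (iTreg), iTreg cultured with vitamin C, natural regulatory T cells (natural Treg) sorted ex vivo, and naive CD4 T cells sorted ex vivo. Per the labels' protocols, 550 ng of total RNA was amplified and labelled with biotin for each array. GenomeStudio 2011.1 is named in the submitters' processing notes. Whether it subtracted background or filtered beads is not given in the sources used here.

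The deposited signal table held a linear intensity and a detection p-value for each of 25697 probes on each array, per the file headers. The median deposited intensity was 144 for conventional iTreg, 157 for vitamin C iTreg, 135 for natural Treg and 132 for naive CD4, so the arrays had not been brought to a common scale. The second deposited table held log2 values with no stated method. Quantile normalization of the log2 of the deposited intensity gave those values back within 5e-07 on each array, and each of its columns had a median of 7.14. The authors' log2 values thus carried no background correction that the deposited intensities did not.

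The intensities were background-corrected, quantile-normalized over the 4 arrays and put on a log2 scale with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the negative controls inferred from the detection p-values. Later steps ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Quantile normalization gives every array the same distribution, so a shift of most genes in 1 direction would not be seen. The offset pulls differences of dim genes toward 0.

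The array's gene table listed 23978 of the 25697 probes, each with 1 gene symbol, and none with several. The other 1719 probes are unnamed here. Symbols were updated through gene IDs and accessions of a RefSeq table of assembly GRCm38.p6, which matched 23971 probes and altered 8 symbols. The files name no genome build, so no coordinates are given. The named probes covered 16590 genes, and a gene was represented by its probe with the highest mean log2 value over the 4 arrays. Tet1 and Tet2 were not analysed here, since no probe used here carried their names.

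A gene entered a comparison when its probe had a detection p-value under 0.01 on at least 1 of the 2 arrays. At that limit 7603 genes were detected on the conventional iTreg array, 7547 on the vitamin C iTreg array, 7429 on the natural Treg array and 7027 on the naive array. Where 1 array did not detect a gene, its value there was set to the higher of its own value and the lowest detected signal of that array, and the fold is then a lower bound. Such a bound was set to 0 where it pointed against the detected side. Differences are normalized log2 values of the first group minus the second, counted when they reached 2-fold, a log2 difference of 1.

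With 1 array per group, no test of a gene was possible, and no p-value across genes was computed. Each gene list was described by its median difference and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these arrays only. The number of arrays limits the precision of each value, and the only internal check was the agreement of different probes of a gene, which share the RNA, the labelling and the array.

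The named genes followed a rule. In the vitamin C comparison it took the 10 highest and 10 lowest differences among genes detected on both arrays, and the 3 largest bounds in each direction. In the other comparisons it took 6 and 3. It added 13 genes chosen for regulatory T cells, DNA methylation and vitamin C uptake, and the 4 members of each described list that differed most. Provisional gene models were not named. The main setting, this rule, 28 gene lists and 8 alternatives were fixed before the data were examined. The alternatives left out background correction, used an offset of 50, replaced quantile normalization by median centring, took the authors' normalized values, set the detection limit at 0.05, required detection on both arrays, dropped the detection filter and its bounds, or averaged the probes of a gene. Chosen after the data were seen were 3 further gene lists, a restriction to genes with a mean log2 value of 8 or more, 2 lists of cell type markers, and the margins within which a value counts as the same. Those margins were a bootstrap interval of the list median from 2000 draws, a multiple of the disagreement between probes for genes, a factor of 1.5 for the correlation across genes, and 10 percentage points for probe agreement.

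The steps were tested on simulated arrays for vitamin C iTreg over conventional iTreg, with log2 noise of SD 0.15 and 798 simulated negative controls, in which 7826 genes were compared. The changed genes were drawn from those detected on the conventional array. Of 100 genes with a true log2 difference of 1.5 in either direction, 89 were called at 2-fold in the right direction, and of 100 with 2.5, 95 were called. Of 7606 compared genes without a true difference, 7 reached 2-fold. A list of genes shifted by 0.5 log2 lay at the 100th percentile, and 6 of 200 lists of unshifted genes lay outside the 2.5 to 97.5 percentile range. Those 200 were random draws of independently simulated genes, so a rate near the nominal one was built in. They do not cover lists of genes that vary together. The simulated noise covers measurement within an array and not differences between cultures.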

Results

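The series profiled regulatory T cells, the Foxp3-expressing CD4 T cells that restrain immune responses, from male mice that carry green fluorescent protein (GFP) under the control of Foxp3. Naive CD4 T cells (GFP-negative, CD44 low) were stimulated through CD3 and CD28 at 1 µg/ml of each antibody, with IL-2 at 15 ng/ml and TGF-beta at 10 ng/ml. The cultures ran 5 to 6 days per the sample labels, while the series text gives 5 days, with or without vitamin C at 10 µg/ml, and GFP-positive CD25-positive cells were then sorted as iTreg. Natural Treg (GFP-positive) and naive CD4 cells were sorted directly from lymph node and spleen. There was 1 array per group and no replicate, so each difference below describes a pair of arrays. Across 8236 genes detected on at least 1 array, Pearson's r across genes was 0.989 between both iTreg arrays, 0.946 between natural Treg and naive CD4, and 0.862 between conventional iTreg and natural Treg. Genes are not independent replicates.

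The comparison of vitamin C iTreg with conventional iTreg asked which transcripts differed when vitamin C, a cofactor of iron- and oxoglutarate-dependent dioxygenases, was added to the culture. No Treg signature gene reached 2-fold, and the sort itself selected on Foxp3-driven GFP and on CD25. Foxp3, the lineage-defining transcription factor (probe ILMN_1225330), differed by a log2 value of -0.21, Il2ra, which encodes CD25, by 0.06, and the inhibitory receptor Ctla4 by 0.08. Tnfrsf18 differed by -0.43 and Ikzf4 by -0.18, while Ikzf2 was not detected on either iTreg array. Of 22 compared Treg signature genes, 0 reached 2-fold, and those that differed most were Cd83 (-0.99), Ebi3 (-0.84), Nrp1 (-0.83) and Swap70 (-0.51). The median of that list was 0.02 and its mean -0.12, opposite in sign. Over the settings the median was -0.0036 at its lowest.

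Of 7756 genes compared, 73 were at least 2-fold higher and 63 at least 2-fold lower on the vitamin C array, and 93.9% lay within 1.5-fold. The gene with the highest difference among named genes detected on both arrays was Hdc, the histidine decarboxylase that makes histamine (2.63). Next were Tbx21, the transcription factor T-bet of T helper 1 cells (2.10), the gap junction gene Gja5 (2.06) and the metalloproteinase inhibitor Timp1 (2.01). Tns4 (1.99), Tmprss3 (1.97), Clec2e (1.95), the Fc receptor gamma chain gene Fcer1g (1.91), Myo3b (1.86) and Krt86 (1.77) followed. On the conventional array Hdc (log2 signal 6.60) and Fcer1g (6.29) lay near its lowest detected signal of 6.16. Ubd, a ubiquitin-like modifier, was at least 7.63-fold higher, Plekha6 at least 2.90-fold and Enam at least 2.52-fold. The lowest named gene detected on both arrays was Gal, which encodes the neuropeptide galanin (-2.30), then Csn2 (-1.85), Sema4f (-1.76), Mreg (-1.74) and Nkg7, a cytotoxic granule gene (-1.70). Grasp (-1.66), the chemokine gene Xcl1 (-1.64), Rasgrp3 (-1.59), Ggt7 (-1.55) and Tmem51 (-1.49) came next. Aqp9 was at least 5.71-fold lower, Tnfrsf11b at least 3.49-fold, and the oxysterol receptor gene Gpr183 had a bound of -1.59 log2. A second detected probe went the same way in 17 of the 18 genes that reached 2-fold and had one; the exception was Clec2e, whose other probe differed by -0.17. Without background correction the counts were 34 higher and 20 lower.

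**Figure D1:**
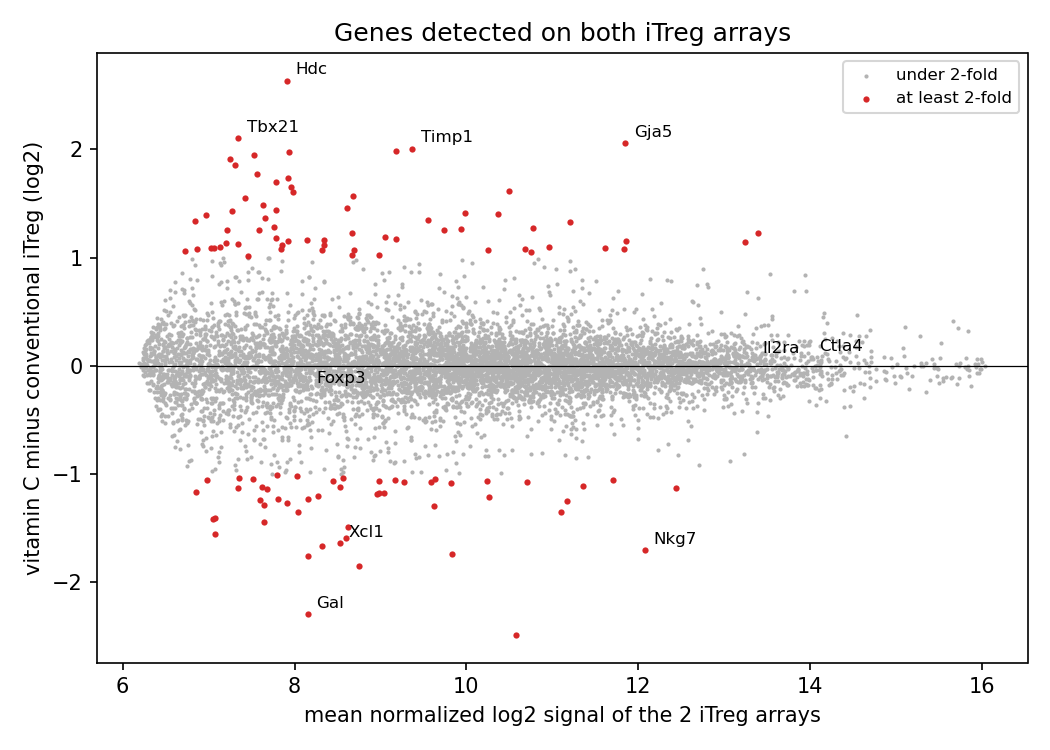
Each point is a gene detected on both iTreg arrays, with the mean normalized log2 signal of both arrays on the x axis and the log2 difference, vitamin C minus conventional iTreg, on the y axis; red points reached 2-fold. Hdc lies at 2.63 and Gal at -2.30, while Foxp3, Il2ra and Ctla4 lie at -0.21, 0.06 and 0.08.

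Cell cycle, quiescence and TGF-beta response genes had small differences that ran mostly in 1 direction. Of 24 cell cycle genes, 23 were above 0 (median 0.16, percentile 99.9), with Cdc6 (0.56), Tyms (0.41) and Cdc20 (0.35) among the largest and the cyclin gene Ccnd2 at -0.46. Another Cdc6 probe, detected on the conventional array alone, went the other way. Of 16 naive and quiescence genes, 14 were below 0 (median -0.20, percentile 0.05), led by the IL-7 receptor gene Il7r (-1.07), Klf2 (-0.77), Klf3 (-0.76) and Lef1 (-0.57). Of 15 TGF-beta response genes, 12 were below 0 (median -0.21, percentile 0.16), among them Smad3 (-0.82) and the inhibitors of DNA binding Id3 (-0.59) and Id1 (-0.39). The interferon response genes were mixed, with 8 of 15 above and 7 below 0, and 4 were at least 2-fold higher, namely Gbp2 (1.23), Oasl2 (1.16), Irf1 (1.14) and Gbp3 (1.08). That list's median was 0.19 (percentile 99.94), outside the random range in 8 of 9 settings and -0.013 without the detection filter.

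No compared gene of the DNA methylation and demethylation lists reached 2-fold, and no TET enzyme was among those compared. Of 10 compared genes of the TET and DNA demethylation list, 4 were above and 6 below 0, with Gadd45g at -0.48 and Gadd45a at -0.41. Tet3 was not detected on either iTreg array, and Tet1 and Tet2 had no named probe. Dnmt1, which maintains methylation, differed by 0.33, and Dnmt3b by -0.31, while Dnmt3a was not detected. The 7 compared genes of the DNA methylation list had a median of 0.21 (percentile 98.99), outside the random range in 8 of 9 settings, and 0.11 without the detection filter. Of them, 5 were above and 2 below 0, and Zbtb38 and Mbd1 differed most. Of 11 iron- and oxoglutarate-dependent histone demethylases, 8 were below 0, with Kdm6b at -0.48. The vitamin C transporter gene Slc23a2 differed by 0.34.

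The other lists had medians inside the random range in the main setting, apart from the CD8 T and NK cell markers. Oxidative phosphorylation (median 0.07), sterol synthesis (0.10), antioxidant genes (0.05), prolyl and lysyl hydroxylases (0.05), and checkpoint and costimulatory receptors (0.06) were slightly above 0. The 2 genes of that last list at least 2-fold higher were Cd86 (1.28) and Lag3 (1.10). HIF targets and glycolysis (-0.02), T cell identity (-0.04), T helper lineage transcription factors (-0.06), effector cytokines and cytotoxic genes (-0.10) and early activation genes (-0.10) were slightly below 0. HIF targets and glycolysis, T cell identity and effector genes rose above 0 under an alternative, to at most 0.02, 0.03 and 0.05. Early activation genes moved to -0.20 (percentile 0.055) with no detection filter, and oxidative phosphorylation and sterol synthesis to 0.15 and 0.16 with median centring. These lists lay outside the random range in 3, 3 and 4 of 9 settings. Stat4 (-1.03), Xcl1 and Il3 (-1.12) were at least 2-fold lower in those lists, and Tbx21 was higher. The unfolded protein and amino acid response had a median of -0.03, with Trib3 at -1.13 and Asns at -0.92. Vitamin C and glucose transporters (-0.18) and the genes with Treg-specific demethylated regions (-0.18) had 5 compared members each, and moved to -0.0085 and -0.03 with the probes of a gene averaged. The means of T cell identity and of the T helper factors were above 0, opposite to their medians. The antioxidant gene Gsta4 was at least 2-fold higher (1.60). Chemokine and homing receptors had a median of 0.00 and a mean of -0.05, reference genes a median of -0.03 and a mean of 0.01, and sex-linked genes a median of -0.21. Among markers of other cells, the 2 compared of 12 B cell genes with a probe, Cd74 (-0.30) and H2-Ab1 (-0.16), were lower. The 3 compared of 13 myeloid genes with a probe (Fcer1g, Cst3 and Ctss) were higher. Their median was 0.26, and -0.035 at its lowest over the settings. The remaining B cell and myeloid genes were detected on neither iTreg array. Of 3 compared CD8 T and NK cell genes, Nkg7 and Klrd1 (-0.98) were lower and Cd8b1 (0.56) was higher. The median of those 3 was -0.98, and -0.05 without the detection filter. No erythroid marker was detected on either iTreg array.

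The second question was whether vitamin C iTreg differed from conventional iTreg along the axis that separates natural Treg from naive CD4. The naive cells were gated CD44 low, so that axis mixes Treg identity with the CD44 gate. Of the 413 genes at least 2-fold higher in natural Treg than in naive CD4 and compared in both, 211 were higher and 200 lower on the vitamin C array. Their median difference was 0.04, above the random range of -0.03 to 0.02. Without background correction it was 0.013 (percentile 95.6), inside that setting's random range. The 103 genes at least 2-fold lower in natural Treg had a median of -0.04, inside the random range of -0.06 to 0.05. With median centring it was -0.056 (percentile 1.79), and with no detection filter -0.056 (percentile 0.76), both outside. Across 7102 genes, Pearson's r between the vitamin C difference and the natural Treg over naive difference was 0.03, and Spearman's rho was 0.04.

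Natural Treg was compared with conventional iTreg to describe how induced and ex vivo Treg differ. Interferon response genes were higher in natural Treg, with 17 of 19 at least 2-fold higher (median 2.31, and 1.54 with detection on both arrays), among them Ifit3 (4.43), Usp18 (4.41) and Rsad2 (at least 33.3-fold). Sterol synthesis genes were lower, 14 of 18 at 2-fold (median -2.07), including Cyp51 (-3.18) and the desaturase gene Scd1 (at least 135.0-fold lower). Cell cycle genes were lower too, 18 of 23 at 2-fold (median -1.72), with Cdk1 at -3.84 and Top2a at -3.45, and so were 12 of 18 HIF targets and glycolysis genes (median -1.25), with Hk2 at -2.30. Of 25 Treg signature genes, 12 were higher and 5 lower at 2-fold: Ikzf2, which encodes Helios, was at least 21.0-fold higher, Klrg1 at least 16.7-fold and Itgae 2.60 log2 higher, while Il2ra was at -1.55. Foxp3 (-0.18) and Ctla4 (0.08) were at similar levels. The iTreg were sorted for CD25 as well as GFP, and natural Treg for GFP, so the lower Il2ra cannot be told apart from the gates. The iTreg were also stimulated in culture, while natural Treg were sorted directly. No difference between these arrays can therefore be told apart from culture. In natural Treg over naive CD4, both sorted directly, the sterol synthesis median was 0.035 and that of HIF targets and glycolysis 0.079. There the interferon response median was -0.02 and the cell cycle median 0.83.

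In all, 963 genes were at least 2-fold higher and 893 lower of 8031. Outside the interferon list, the highest named genes detected on both arrays were the innate sensor gene Nod1 (5.76), Cyria (4.54), Plac8 (4.41) and Nsg2 (4.41), with Sytl2 at least 62.9-fold and Ly6c1 at least 47.2-fold higher. The lowest detected on both were Gja1 (-6.31), Bdh2 (-6.18), Denn2b (-6.03), Igfbp7 (-5.75), the metallothionein gene Mt1 (-5.59) and Slco4a1 (-5.27). Of 17 naive and quiescence genes, 8 were higher and 2 lower at 2-fold and 5 were below 0 (median 0.91), with Klf3 at 2.58. Of 17 checkpoint and costimulatory receptors, 10 were higher and 1 lower at 2-fold (median 1.27), with Btla at 2.21. B cell markers were mixed, with Cd79b at least 14.0-fold higher and H2-Ab1 at -2.55, so that their median of 1.19 became -1.88 when detection on both arrays was required.

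**Figure D2:**
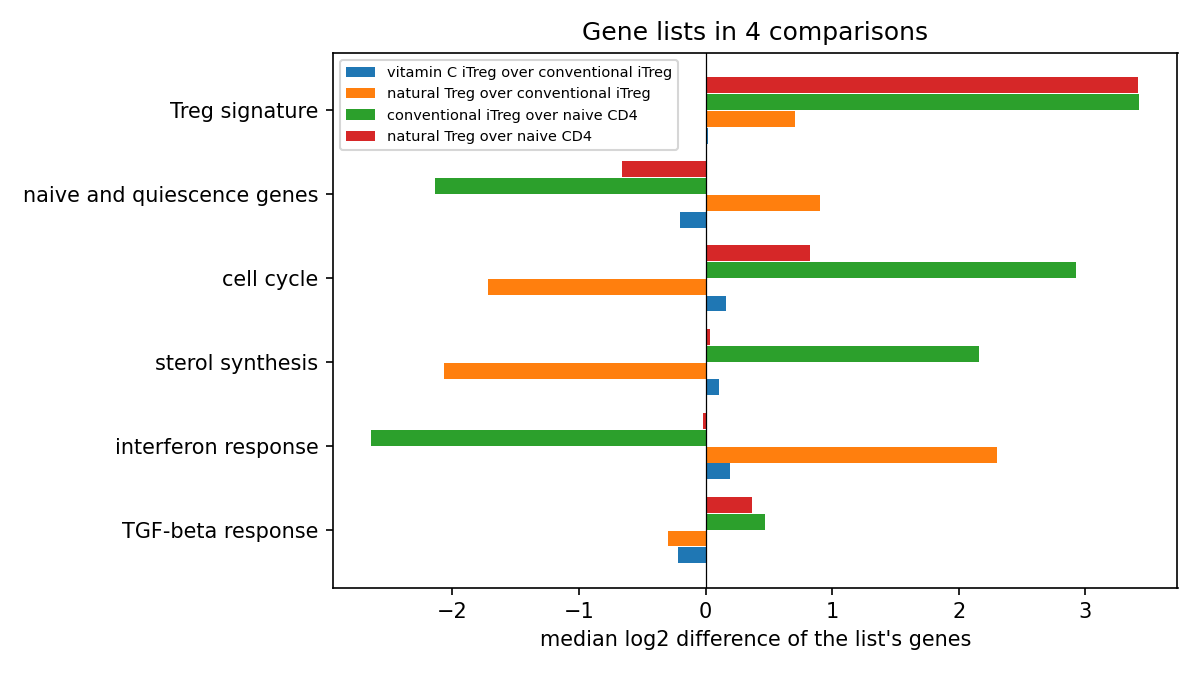
Bars give the median log2 difference of the genes of 6 lists (x axis, log2) in 4 comparisons (colours). The interferon response list had a median of 2.31 in natural Treg over conventional iTreg and -2.64 in conventional iTreg over naive CD4, against 0.19 in vitamin C over conventional iTreg.

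Conventional iTreg was compared with naive CD4, the cell type it was grown from. Of 22 Treg signature genes, 19 were at least 2-fold higher (median 3.42): Socs2 at least 262-fold, Il2ra at least 102.0-fold, Nrp1 by 5.45 log2, and Foxp3 at least 3.07-fold. The iTreg were sorted for Foxp3-driven GFP and CD25, and the naive cells as GFP-negative. The sort itself thus favoured higher Foxp3 and Il2ra. The iTreg were also stimulated through CD3 and CD28 with IL-2, and no array was of cells stimulated without TGF-beta. Treg induction and activation in culture thus cannot be told apart in this comparison. Cell cycle (19 of 23, median 2.92, and 1.94 with probes averaged), sterol synthesis (15 of 18, median 2.16) and HIF targets and glycolysis (13 of 18, median 1.35) were higher, with Birc5 at 4.94, Scd2 at 3.57 and Hk2 at 5.38. Interferon response genes were lower (14 of 19, median -2.64, from -3.16 to -1.39 over the 9 settings), with Ifit3 at -4.76 and Oasl2 at -4.73, as were naive and quiescence genes (10 of 17, median -2.14, and -1.02 without the detection filter), with Il7r at -3.72. In all, 1051 genes were higher and 1174 lower of 7963; among those detected on both arrays they were led by the prion protein gene Prnp (7.07), Rgs16 (6.31) and Slc9b2 (5.74) above, and Tdrp (-5.41), Cyria (-5.34) and Nsg2 (-4.77) below. Only 642 of the higher genes were detected on both arrays, so 409 rest on a bound. B cell markers had a median of -1.43, which became 2.39 when detection on both arrays was required.

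Natural Treg, sorted as GFP-positive, was compared with naive CD4, sorted as GFP-negative and CD44 low. The sort itself thus favoured higher Foxp3 and Cd44 in natural Treg, and Treg identity cannot be told apart from the CD44 gate. All 25 compared Treg signature genes were at least 2-fold higher (median 3.42). Itgae, the integrin CD103 (6.77), Nrp1 (5.59), Ctla4 (5.25), Cd83 (5.18), Rgs1 (5.12) and Tiam1 (4.33) were the highest genes detected on both arrays, and Foxp3 was at least 2.72-fold, Ikzf2 at least 15.0-fold and Ccr6 at least 81.0-fold higher. The lowest detected on both were Lypd6b (-3.65), Nacc2 (-3.38), Dapl1 (-3.34), Als2cl (-3.34), Arhgap29 (-3.25) and Tdrp (-2.89), and Pdlim4 had a bound of -6.61 log2. Interferon response genes went both ways (median -0.02, mean 0.01, opposite in sign, 9 above and 10 below 0). Of 5 B cell markers, Cd79b (2.37) and Cd74 (1.60) were at least 2-fold higher and 3 were below 0 (median -0.35, mean 0.45, opposite in sign). Of 3 CD8 T and NK cell markers, 1 was higher and 1 lower at 2-fold (median -0.56). Cell cycle genes (21 above and 2 below 0, median 0.83) and early activation genes (15 above and 1 below 0, median 0.53) were also higher. Chemokine and homing receptors had 8 above and 2 below 0, with Cd44 at 2.16. Their median was 0.96, and 0.09 at its lowest over the settings. In all, 457 genes were higher and 154 lower of 7582. Of the higher ones, 291 were detected on both arrays, and the lower count was 85 without background correction.

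**Figure D3:**
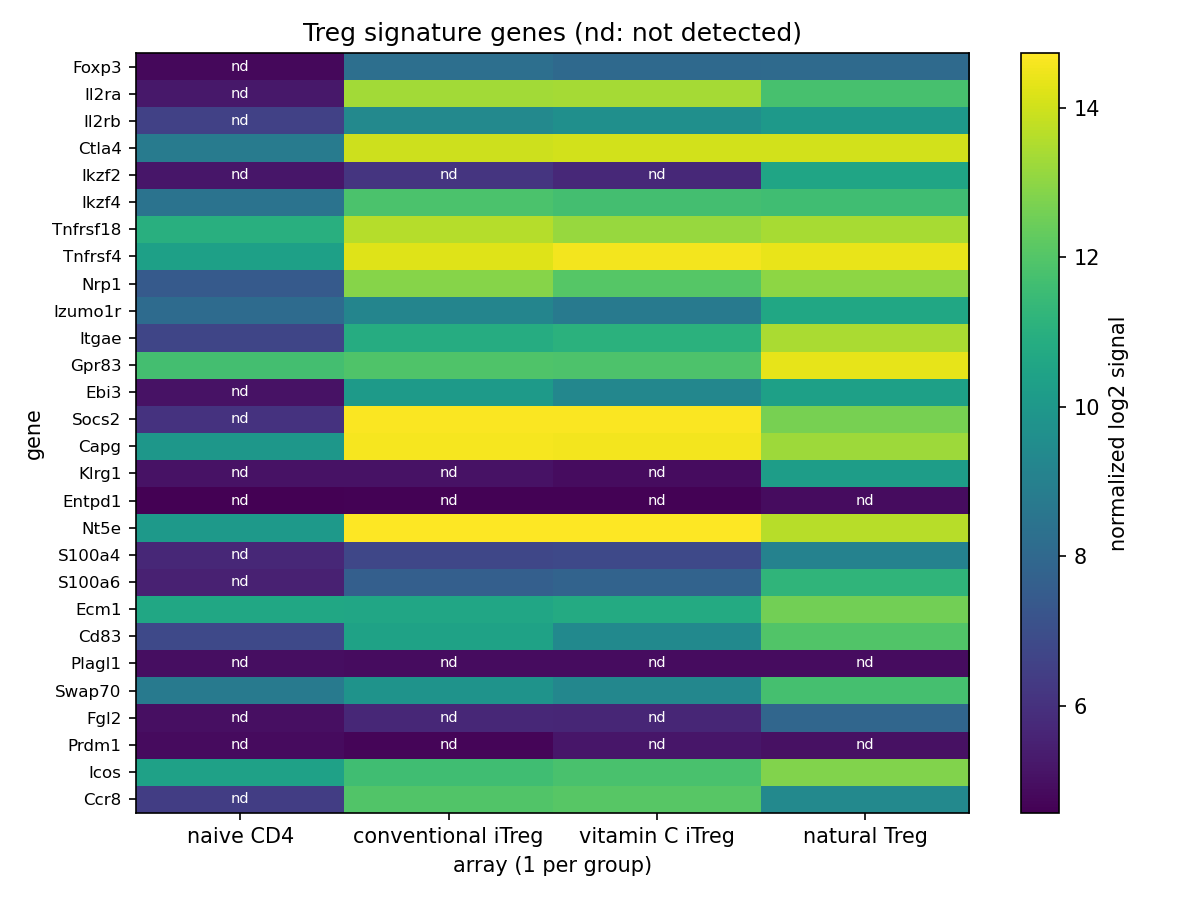
Colour gives the normalized log2 signal of the 28 Treg signature genes (rows) that had a probe, on the 4 arrays (columns, 1 per group), and nd marks a gene not detected. Of 22 genes compared between both iTreg columns, 0 reached 2-fold, and Ikzf2 and Klrg1 are detected in the natural Treg column alone.

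Natural Treg against vitamin C iTreg shares its natural Treg array with the comparison against conventional iTreg. It gave 1048 genes at least 2-fold higher and 943 lower of 8034. Interferon response genes were higher (14 of 19, median 2.28), and sterol synthesis (14 of 17, median -2.54) and cell cycle genes (18 of 24) were lower. Of 25 Treg signature genes, 12 were higher and 5 lower at 2-fold, with Ikzf2 at least 20.6-fold higher and Il2ra at -1.62. Here too the CD25 gate of the iTreg cannot be told apart from the difference in Il2ra. As with conventional iTreg, the differences cannot be told apart from culture against direct sorting. The gap junction gene Gja1 was the lowest named gene detected on both arrays (-6.61), and Ly6c1 the highest (5.36). Pearson's r across 8236 genes was 0.856, against 0.862 for conventional iTreg. B cell markers had a median of 1.16, which became -1.65 when detection on both arrays was required.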

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

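The look at probes without a gene name was chosen after the data had been seen. A signal outside the genes compared stood out among the 1719 probes that carry no gene name here, of which 689 were detected on at least 1 iTreg array. Probe ILMN_2742861 was 3.79 log2 higher on the vitamin C iTreg array than on the conventional iTreg array, more than any named gene detected on both. Its deposited intensity was 3954 on the vitamin C array, 380 on the conventional array, 332 on the natural Treg array and 153 on the naive array. With undetected values treated as for genes, 7 such probes were at least 2-fold higher and 9 at least 2-fold lower on the vitamin C array.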

How the results depend on the processing

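No paired analysis was possible because each group had 1 array. The alternatives other than the restriction to a mean log2 of 8 or more were planned, and that restriction was chosen after seeing the data. Of 82 gene counts under alternatives, 71 stayed within 1.5 times the main count. With median centring, natural Treg over conventional iTreg had 764 genes higher and 1072 lower, so the direction with more genes changed. It also changed for conventional iTreg over naive CD4 (1209 higher, 972 lower) and natural Treg over vitamin C iTreg (826 higher, 1144 lower). The correlation across genes of 0.03 stayed above 0 under all 8, and was lowest at 0.0094 with no detection filter and highest at 0.046 with median centring. For vitamin C over conventional iTreg, the 73 higher genes became 34 with no background correction and 34 with the authors' normalized values, which are the same numbers since that table holds the uncorrected values. All 34 were among the 73. The 63 lower genes became 20 and 20 under those alternatives, and 99 with no detection filter. With a mean log2 of 8 or more, 32 were higher and 35 lower. Detection on both arrays lowered the higher count from 1051 to 642 for conventional iTreg over naive CD4, and from 457 to 291 for natural Treg over naive CD4, by construction, since bounds were left out. The 154 genes lower in natural Treg than naive CD4 became 85 with no background correction and 85 with the authors' normalized values; the cause was not tested. Of 1245 list medians under alternatives, 40 moved and 5 reversed. A list counted as reversed only if its main median lay outside the random range and changed sign. Other medians changed sign uncounted, such as vitamin C and glucose transporters in natural Treg over conventional iTreg, from 0.18 to a lowest value of -1.11. Reversed were the interferon response in vitamin C over conventional iTreg (-0.013) and CD8 T and NK cell markers in natural Treg over conventional iTreg (0.041), both with no detection filter. B cell markers reversed where detection on both arrays was required, to -1.88 in natural Treg over conventional iTreg, 2.39 in conventional iTreg over naive CD4 and -1.65 in natural Treg over vitamin C iTreg, where fewer members were left. Of 4730 named-gene values under alternatives, 633 moved and 0 reversed. A gene counted as reversed only if its main difference reached 2-fold, so changes of sign in smaller differences were not counted. By signal over background, 69 of the 1893 compared genes with a mean log2 under 8 reached 2-fold in the vitamin C comparison. So did 54 of the 3506 from 8 to under 11, and 13 of the 2357 at 11 or more. The cause was not tested. Of the 8834 genes detected on neither iTreg array, 12 reached 2-fold. Those genes were selected for low signal on both arrays, so that count gives no noise level for the compared genes.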

Other observations

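The tests of single probes, of other cells, of unconverted naive cells, of vitamin C and of culture were chosen after the results had been seen, and so were the 3 gene lists described next. Genes induced by interferon-gamma were higher on the vitamin C iTreg array: of 22 compared, 10 reached 2-fold, 20 were above 0, and the median was 0.87 (0.53 without the detection filter), with Ubd, Gbp2 (1.23), Irf1 (1.14) and Gbp3 (1.08) among them. The list was written after the genes at 2-fold had been seen and holds 10 of them, so its median is not independent evidence. Of its 12 members under 2-fold, 10 were above 0, with a median of 0.41. They belong to a list written after the results had been seen, so they are not independent evidence either. Type I interferon genes did not go with it, with 13 compared, a median of -0.136 and percentile 3.03. Oasl2 (1.16) was the exception at 2-fold. The median lay inside the random range of -0.140 to 0.130 in the main setting, and outside it in 1 of 9 settings. This list too was written after the results had been seen, so its parting from the interferon-gamma list here is not independent evidence. In natural Treg over naive CD4 the lists also parted, with 20 of 22 interferon-gamma-induced genes above 0 (median 0.20) and 15 of 20 type I genes below 0 (median -0.31). Both lists were higher in natural Treg than conventional iTreg (medians 0.99 and 2.85) and lower in conventional iTreg than naive CD4 (medians -0.62 and -3.03). Over the 9 settings the interferon-gamma list ran from 0.64 to 1.04, from -0.66 to -0.36, and from 0.09 to 0.20 in natural Treg over naive CD4. Ifng itself was not detected on either iTreg array. Targets of ATF4, a transcription factor of the amino acid response, were lower on the vitamin C array, with 15 of 18 below 0 and a median of -0.50. Of these targets, 3 reached 2-fold. The 15 under 2-fold had a median of -0.39. Since this list too was written after the results had been seen, neither median is independent evidence.

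Hdc (2.63) and Fcer1g (1.91) are also expressed by mast cells and basophils. All 9 mast cell and basophil markers with a probe were undetected on the vitamin C iTreg array, Mcpt8, Cpa3 and Fcer1a included. They were undetected on the other arrays too, so no array shows that these probes work. Their absence thus cannot exclude a small share of such cells. Hdc was detected on all 4 arrays, with a log2 signal of 7.56 on the naive array and 6.86 on the natural Treg array. The markers were listed after Hdc and Fcer1g had been seen, and a sort for GFP and CD25 preceded the RNA extraction.

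The higher interferon-gamma-induced genes were weighed against 3 technical explanations. Error of single probes would leave the 12 members under 2-fold inside the random range of -0.13 to 0.11, and their median was 0.41. The list was written after the results had been seen, so this median cannot exclude such error. For Gbp2, Gbp3 and Irf1, 5 further probes went the same way. Under 4 alternatives of normalization or background, 2 of them with the same values, the smallest median was 0.81, above the random range in each. The list holds 10 genes already seen at 2-fold on these arrays, so this outcome was likely in advance. It cannot exclude normalization or background. More B or myeloid cells would raise their abundant transcripts, and 0 of 5 (Cd74, H2-Ab1, Lyz2, Tyrobp and S100a8) were detected and 1.5-fold higher. But 3 were undetected on every array and the others had a high baseline. Fcer1g, Cst3 and Ctss, the 3 compared of 13 myeloid markers with a probe, were above 0. This explanation stays open. The sort for Foxp3-driven GFP and CD25 selected against such cells, but its purity is not known here. The B cell marker Cd79b was undetected on both iTreg arrays, but had a log2 signal of 9.97 on the GFP-sorted natural Treg array. With 1 array per condition, vitamin C and any other difference between the cultures cannot be told apart either.

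Quiescence genes, led by Il7r and Klf2, were lower on the vitamin C array. Fewer unconverted naive cells would lower naive-enriched genes by a like share of their naive signal. The sort for GFP and CD25 selected against these GFP-negative cells, but its purity is not known here. For the 15 quiescence genes detected on both iTreg arrays, the excess on the conventional array had a median of 4.18% of the naive signal, and for 34 genes at least 4-fold higher in naive CD4 than in natural Treg it was 0.079%, with an upper quartile of 1.37%; both the 34 genes and the 4.18% bar replaced earlier choices made on genes picked by the outcome. The list median stayed below the random range under the 4 alternatives of normalization or background, at -0.17 nearest to 0. Vitamin C may account for the difference, which 1 array per condition leaves open.

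Interferon response genes as a list were higher on the natural Treg array than on both iTreg arrays, and higher on the naive array than on the conventional iTreg array. The naive and vitamin C iTreg arrays were not compared. In natural Treg over conventional iTreg the smallest median of the interferon response genes under the 4 alternatives of normalization or background was 1.84, above the random range. Culture against freshly sorted cells may account for their higher level, but 0 cultured arrays were other than iTreg, so culture and the induced state cannot be told apart.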
